A study of Rattus norvegicus with 11 samples.

How the data were processed

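RNA of dorsal root ganglia from Sprague-Dawley rats was sequenced in 11 libraries of 3 groups: sham operation (Sham, n = 4), spinal nerve ligation (SNL, n = 4) and spinal nerve ligation followed by UNC0638 (SNL plus UNC0638, n = 3). Per the labels, total RNA was extracted with either of 2 reagents, Trizol or RNeasy, and which sample received which is not given in the sources used here, so that the reagent and the group cannot be told apart. Stranded total RNA libraries were made after removal of ribosomal RNA and sequenced as single-end reads of 50 bases on an Illumina HiSeq 2500. Per the labels, Sham ganglia were from the right side and both ligated groups from the left side. The authors aligned the reads to the rat genome build rn4 with TopHat (TopHat2 2.0.9) and named Cuffdiff 2.1.1 as a processing tool. The annotation that was counted, the use of strand and the assignment of reads shared between genes are not given in the sources used here.

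The deposited signal values are gene counts that the authors scaled to a common library size with 1 factor per library before deposit. They are not raw counts. In each library the low values were whole multiples of a single step, within 0.01 steps, for 98.9% to 99.2% of them, and the step (0.429 to 1.56) was taken as the value of 1 read. The totals were 9450045 to 11347920 per library, the reads estimated from them 6127898 to 24367778, and the genes above 0 numbered 13057 to 13713. The 10 genes with the highest values held 5.78% to 7.98% of a library. The same groups' replicates differed by 5.90 to 80.7 times the counting noise of the estimated reads. Separate libraries are expected to exceed counting noise, and the effect of depth on the calls was not tested.

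The table held 16811 genes, identified by symbol alone. Of these, 1970 were at 0 in every library, 24 had names altered to dates, 14003 names were current symbols in the reference annotation and 2345 were synonyms there. That annotation belongs to a later genome build than the data, so that no positions, lengths or base compositions were used. The genes Sdc2 (at 0 in all SNL libraries, 336 to 548 in the others) and Pcdhgc5 (at 0 in all SNL plus UNC0638 libraries, 45.0 to 175 in the others) were left out after their values were seen. Genes with a value of at least 10 in at least 3 libraries were tested (12085).

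A test for counts had been chosen before the data were examined, with limma-trend named for the case that the values were not counts. As they are scaled values, limma (3.58.1, R 4.3.3) was fitted to log2(value + 1) with a mean per group over all 11 libraries, with eBayes (trend and robust, statmod 1.5.0). The comparisons were SNL against Sham, SNL plus UNC0638 against SNL and SNL plus UNC0638 against Sham. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes carry the added 1 and understate the change of genes with low values. SE is that of the moderated fit. The 31 gene lists were written before the data were examined, from marker genes of the cells of the ganglion and gene families; a list of mitochondrially encoded genes was not analysed here. Each list gave the number of members called, adjusted over all genes and adjusted over the list alone, the median log2 fold change, and limma's camera against all other genes with a preset correlation of 0.01, adjusted over 93 tests. With a correlation estimated from the residuals, no list was called by camera in any comparison.

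The genes named were fixed by a rule before the data were examined. Per comparison it takes the 6 highest and the 6 lowest log2 fold changes among called genes with a mean of at least 1 CPM (counts scaled to the library total) and no overlap between the libraries of both groups. Per list it takes the 4 called members with the smallest p (8 for potassium channel genes), or up to 2 abundant members where none was called. In every comparison it adds Ehmt2, Ehmt1, Kcna4, Kcnd2, Kcnma1, Atf3, Oprm1 and Cnr1. A further gene of this rule, a list that holds it and some list members are not reported here. The slope of the differences with UNC0638 on those of ligation was computed over all tested genes with the 4 SNL libraries split in pairs, and on 100 simulated data sets without an effect. The noise of these data sets was independent between genes and libraries. The position of a library on a gene is its value minus the Sham mean, over the SNL mean minus the Sham mean, on the scale of the values. A Sham or SNL library was left out of the mean of its own group for this. Intervals of median positions are from 1000 bootstrap draws over genes.

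Alternatives set before the data were examined were median-of-ratios and upper-quartile scaling, no filter, a filter at 1 CPM in 3 libraries, limma-voom with quality weights on the estimated reads, eBayes without robust estimates, only the 2 groups compared, the replicate number as a block, limma's treat against a 1.2-fold change, an adjusted p under 0.01, an estimated camera correlation and each library left out in turn. Chosen after the data were seen were TMM scaling, pseudocounts of 0.5 and 10, leaving out Sham and SNL replicates 3, leaving out these and SNL plus UNC0638 replicate 1, and a model term setting Sham replicate 3, SNL replicate 3 and all SNL plus UNC0638 libraries apart. The scalings were computed in R, and tables were prepared with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3). Replicate numbers gave no clear pairing of the libraries: of 10 same-numbered pairs, 2 had deviations from their group means correlated above 0.1. Those of Sham with SNL had correlations of 0.187, 0.005, 0.431 and 0.096 for replicates 1 to 4, so that a pairing of these 2 groups is not excluded. The pipeline was tested on simulated data with known changes: it recovered 16.4% to 28.4% of 1.5-fold, 52.2% to 61.2% of 2-fold and 81.8% to 90.9% of 4-fold changes, with 4.46% to 8.40% false calls and 0 calls of the wrong sign. Genes and libraries were drawn independently there, so that these rates do not cover deviations of a library shared across genes. Per comparison, 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, of 11960 to 11970 run. In the data 27.8% to 51.5% of the genes were called. The adjusted threshold depends on the share of changed genes, so that the recovered shares are not the sensitivity in these data. A known position of 0.5 was recovered as 0.496 to 0.507, and a known slope of -0.49 as -0.44.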

Results

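RNA of dorsal root ganglia, which hold the cell bodies of the sensory neurons of the body, was sequenced from Sprague-Dawley rats in 11 libraries. The 3 groups were sham-operated rats (Sham, n = 4), rats with a spinal nerve ligation (SNL, n = 4), an injury used as a model of neuropathic pain, and ligated rats given UNC0638 (SNL plus UNC0638, n = 3). UNC0638 is an inhibitor of the histone methyltransferases G9a (gene Ehmt2) and GLP (gene Ehmt1). Sham ganglia came from the right side and all ligated ganglia from the left side, and no group received UNC0638 without ligation, per the labels. The deposited values were gene counts scaled to a common library size, with totals of 9450045 to 11347920 per library. The reads behind these totals were estimated, from the step between the lowest values of a library, at 6127898 to 24367778 per library. Of the genes in the table, 12085 had a value of at least 10 in at least 3 libraries and were tested. Values are means ± SD of scaled counts over the libraries of a group. Within groups, replicates differed by 5.90 to 80.7 times the counting noise. The labels do not say that the replicates were separate animals, and p-values refer to the spread between these libraries.

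The first principal component of the tested genes held 53.8% of the variance and separated Sham libraries (-71.0 to -47.8) from SNL libraries (23.2 to 56.7). SNL plus UNC0638 replicates 2 and 3 lay at 41.2 and 44.1, and replicate 1 at -9.04. The second component held 26.5% and set the SNL plus UNC0638 libraries (-57.8 to -40.8) apart from the others (-24.4 to 45.7). The mean level of the injury and regeneration genes in SNL plus UNC0638 replicate 1 was 0.30 above Sham on the log2 scale, against 1.69 and 2.18 in replicates 2 and 3. Skeletal muscle genes stood 6.93 above Sham in that replicate, against 0.06 and -0.73 in the others. Sham replicate 3 and SNL replicate 3 deviated from their group means in like fashion across genes (r = 0.431 over genes, which are not independent replicates).

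SNL was compared with Sham to show what the ligation changed. Nerve injury genes of the ganglion rose steeply: the transcription factor Atf3, a marker of injured sensory neurons, went from 169.8 ± 7.80 to 6267 ± 1141 (log2 fold change 5.18, SE 0.52, adjusted p = 0.000101). The neuropeptide genes Vip and Npy went from 7.41 ± 5.01 to 2903 ± 749 and from 13.7 ± 0.879 to 4805 ± 1196. Most potassium channel genes fell. The voltage-gated channel gene Kcna4 went from 906 ± 36.3 to 119.5 ± 65.6 (log2 fold change -3.04, SE 0.30, adjusted p = 0.000101), 8.24-fold lower. Markers of uninjured nociceptors fell, among them the sodium channel gene Scn11a from 9128 ± 1555 to 699.9 ± 588 (log2 fold change -4.00, SE 0.43, adjusted p = 0.000106). Most markers of macrophages, of T and NK cells, of fibroblasts and of dividing cells rose. In all, 5823 of 12085 genes passed the test, 2995 higher and 2828 lower, with 1468 and 934 of them changed at least 2-fold.

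The genes with the highest log2 fold changes were Crisp1 (8.60), Vip (8.57), Npy (8.31), the muscle LIM protein gene Csrp3 (7.69), the transglutaminase gene Tgm1 (7.36) and Hpd (7.20), with adjusted p between 0.000101 and 0.000178. Those with the lowest were Mrgprd (-6.12), Mrgprb4 (-6.04) and Mrgprx1 (-5.29), which encode receptors of the Mas-related family found in small sensory neurons, the nicotinic receptor gene Chrna3 (-5.34), the link protein gene Hapln4 (-5.31) and Sptssb (-5.29). Mrgprd, for example, fell from 251 ± 68.1 to 7.63 ± 13.5. Of the genes tested, 43.3% had no overlap between the libraries of both groups, where chance gives 2.86%.

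Of 79 measured genes with symbols beginning Kcn, which encode potassium channel subunits and their auxiliary proteins, 46 fell and 8 rose (47 and 9 adjusted over the list alone), with a median log2 fold change of -1.28 (camera adjusted p = 5.89e-07, and adjusted p = 0.538 with an estimated correlation). The smallest p-values belonged to Kcna4 and others, among them Kcns3 (1774 ± 187 to 205 ± 122), Kcnip2 (1186 ± 188 to 163 ± 72.9), Kcnab1 (3848 ± 922 to 703 ± 189), Kcnip4 (363 ± 90.6 to 30.1 ± 18.1) and Kcnf1 (353 ± 63.1 to 24.96 ± 17.6). Their log2 fold changes were -3.27, -2.94, -2.45, -3.67 and -3.98. Kcnd2 (44.6 ± 11.99 to 8.58 ± 5.23, log2 fold change -2.36, SE 0.37, adjusted p = 0.000445) and Kcnma1, which encodes the large-conductance calcium-activated channel (768 ± 145 to 332 ± 137, log2 fold change -1.28, SE 0.27, adjusted p = 0.00261), fell too. Voltage-gated sodium channel genes gave 2 higher and 9 lower of 14 (3 and 9), and bracketed counts here and after are adjusted over the list alone. Scn11a, Scn10a (11262 ± 2454 to 1744 ± 1408) and Scn1a (5779.8 ± 296 to 1215 ± 569) fell. Scn3a, the channel gene expressed before birth and after nerve injury, rose from 17.9 ± 5.82 to 66.8 ± 10.6. Calcium channel genes gave 1 higher and 6 lower of 21 (1 and 6). The member with the smallest p, Cacna2d1, whose product binds gabapentin, rose from 2456 ± 113 to 13093 ± 2070.4 (log2 fold change 2.40, SE 0.23, adjusted p = 0.000101).

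Counts in brackets are adjusted over the list alone. Injury and regeneration genes gave 29 higher and 0 lower of 33 (29 and 1), with a median log2 fold change of 2.89 (camera adjusted p = 1.82e-13, and adjusted p = 0.524 with an estimated correlation). Nociceptor markers gave 2 higher and 19 lower of 24 (3 and 19), with a median of -1.81 (camera adjusted p = 5.89e-07, and adjusted p = 0.524 with an estimated correlation). The serotonin receptor channel gene Htr3a, 1 of them, fell from 2649 ± 590.5 to 147 ± 153. Markers of large-diameter sensory neurons gave 0 higher and 14 lower of 18 (0 and 14), with the neurofilament genes Nefl and Nefh at 4.68-fold and 3.70-fold lower. Inhibitory G protein-coupled receptor genes gave 2 higher and 14 lower of 23 (2 and 15). The opioid receptor gene Oprm1 fell from 359.8 ± 54.4 to 95.4 ± 51.7 (log2 fold change -2.08, SE 0.36, adjusted p = 0.000743), and the cannabinoid receptor gene Cnr1 from 644 ± 60.8 to 189 ± 79.8 (log2 fold change -1.86, SE 0.27, adjusted p = 0.000322). TRP, ASIC, P2X, HCN and Piezo channel genes gave 6 higher and 14 lower of 27 (6 and 14), with Trpv1 falling from 2784 ± 372 to 519 ± 256. GABA-A and ionotropic glutamate receptor genes gave 5 higher and 11 lower of 24 (5 and 11). Synaptic vesicle and exocytosis genes gave 2 higher and 13 lower of 24 (3 and 14). Several lists share members, such as Scn10a and Scn11a in the sodium channel and nociceptor lists, Cacna2d1 in the calcium channel and injury lists, Pvalb in the large-diameter neuron and skeletal muscle lists, and Atf3 in the injury and immediate early lists.

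Markers of other cells of the ganglion mostly rose, here with the counts adjusted over the list alone in brackets. Macrophage markers gave 22 higher and 0 lower of 23 (22 and 0), with a median log2 fold change of 2.11 (camera adjusted p = 6.86e-11, and adjusted p = 0.524 with an estimated correlation). Cd74, the invariant chain of class II antigen presentation, went from 1111 ± 517 to 8933 ± 2393 and the fractalkine receptor gene Cx3cr1 from 63.2 ± 22.9 to 260.3 ± 42.8. T and NK cell markers gave 14 higher and 0 lower of 17 (16 and 0). B cell markers gave 3 higher and 0 lower of 3 (3 and 0). Neutrophil markers gave 3 higher and 0 lower of 7 (3 and 0). Interferon response genes gave 12 higher and 1 lower of 28 (12 and 1). Fibroblast and matrix genes gave 19 higher and 0 lower of 19 (19 and 0), with a camera adjusted p of 1.24e-09, and 0.524 with an estimated correlation, with the collagen gene Col1a1 going from 5563 ± 1763 to 27332 ± 9955. Endothelial and mural cell markers gave 12 higher and 0 lower of 16 (12 and 0). Cell cycle genes gave 19 higher and 0 lower of 23 (19 and 0). Immediate early genes gave 15 higher and 0 lower of 17 (16 and 0). Schwann repair genes gave 6 higher and 1 lower of 11 (6 and 1). Myelin genes gave 8 higher and 0 lower of 17 (8 and 0). Satellite glia markers went both ways, 5 higher and 4 lower of 13 (5 and 4), and the filament gene Gfap rose from 265 ± 119 to 2612 ± 582 (log2 fold change 3.36, SE 0.40, adjusted p = 0.000134). Ribosomal protein genes gave 62 higher and 0 lower of 80 (66 and 0), with a median of 0.58 (camera adjusted p = 2.44e-12, and adjusted p = 0.538 with an estimated correlation). Replication-dependent histone genes gave 17 higher and 1 lower of 22 (17 and 1). Cholesterol synthesis genes gave 0 higher and 5 lower of 22 (0 and 5). Red blood cell genes gave 1 higher and 2 lower of 9 (0 and 0). Skeletal muscle genes gave 0 higher and 1 lower of 7 (0 and 1), the 1 being Pvalb (1399.7 ± 304 to 111 ± 169.5, log2 fold change -4.89, SE 0.89, adjusted p = 0.00111), which is also a large-diameter neuron marker. Markers of central oligodendrocytes and astrocytes gave 3 higher and 3 lower of 11 (3 and 3). Germline genes gave 0 higher and 2 lower of 3 (0 and 2). The median and the mean of the skeletal muscle list differed in sign (0.13 and -0.36).

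Enzymes that set or remove histone and DNA methylation gave 11 higher and 2 lower of 25 (12 and 2), the latter adjusted over the list alone. The target genes of UNC0638 rose slightly: Ehmt1 from 441 ± 38.4 to 678 ± 33.3 (log2 fold change 0.62, SE 0.10, adjusted p = 0.000493). Ehmt2 rose from 835 ± 172 to 1134 ± 85.4 (log2 fold change 0.46, SE 0.16, adjusted p = 0.0321). The Ehmt2 call was lost in 6 of 11 fits with a single library left out, those without Sham replicates 1, 2 or 4 or SNL replicates 1, 2 or 3 (adjusted p 0.061 to 0.091), and with the replicate number as a block (log2 fold change 0.46, adjusted p = 0.0507). Ezh2, which methylates another lysine of histone H3 in dividing cells, rose from 53.4 ± 6.24 to 249 ± 25.5. Side of the body differed along with ligation in this comparison.

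**Figure D1:**
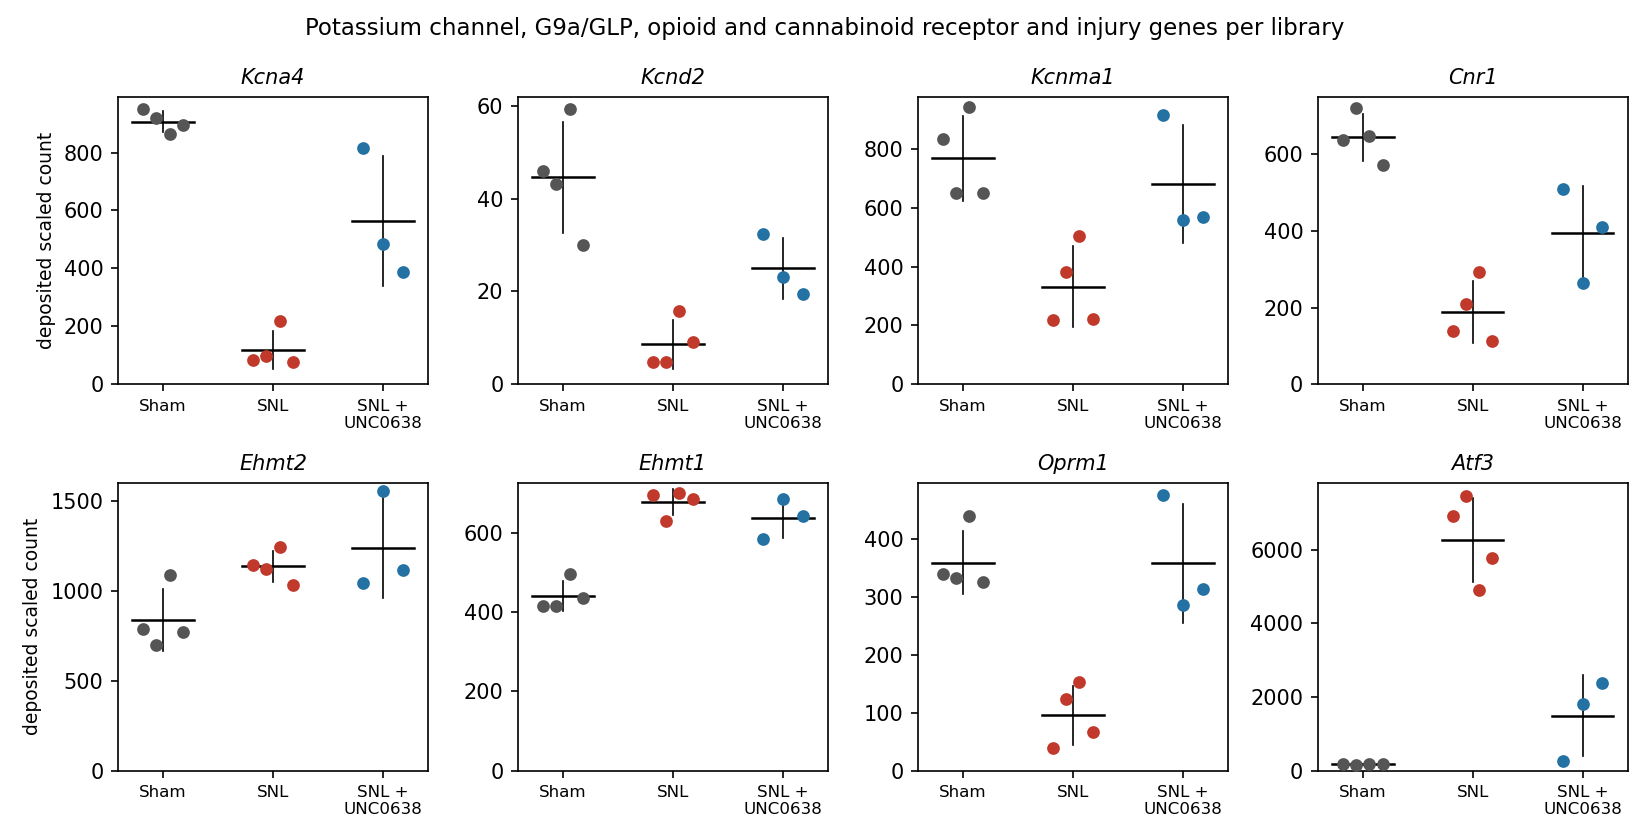
Scaled counts of 8 genes in each library (points) by group, with group means (horizontal lines) and SD (vertical lines), each panel on its own linear axis from 0. Kcna4 fell from 906 ± 36.3 in Sham to 119.5 ± 65.6 in SNL and stood at 563 ± 225 in SNL plus UNC0638, while Atf3 went the other way.

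SNL plus UNC0638 was compared with SNL to show what differed in ligated ganglia with the inhibitor, the comparison closest to the title of the series, which concerns G9a and potassium channel genes. Of 79 potassium channel genes 45 were higher with UNC0638, a number that fell to 29 without SNL plus UNC0638 replicate 1 and to 14 with a model term that set Sham replicate 3, SNL replicate 3 and all SNL plus UNC0638 libraries apart. Kcna4 stood at 563 ± 225 against 119.5 ± 65.6 (log2 fold change 2.29, SE 0.33, adjusted p = 0.00107), 4.88-fold higher. Oprm1 stood at 359 ± 103 against 95.4 ± 51.7 (log2 fold change 2.05, SE 0.38, adjusted p = 0.00358). Injury genes were lower, with Atf3 at 1487 ± 1098 against 6267 ± 1141 (log2 fold change -2.56, SE 0.56, adjusted p = 0.00743). Atf3 was at 265, 1802 and 2393 in SNL plus UNC0638 replicates 1, 2 and 3, all below the lowest SNL library (4914). The size of its change thus rests in large part on replicate 1. The inducible nitric oxide synthase gene Nos2, near 0 in both other groups, stood at 246 ± 137 (log2 fold change 7.01, SE 0.57, adjusted p = 0.000105). In all, 3356 genes passed, 1630 higher and 1726 lower, with 879 and 354 of them changed at least 2-fold.

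Of the 79 potassium channel genes, 45 were higher and 2 lower (47 and 4 adjusted over the list alone), with a median log2 fold change of 1.08 (camera adjusted p = 5.09e-10, and adjusted p = 0.524 with an estimated correlation). The smallest p-values belonged to Kcng4 (114 ± 42.9 in SNL and 532 ± 115 with UNC0638), Kcna4, the sodium-activated channel gene Kcnt1 (256 ± 56.6 and 693 ± 181) and Kcnip2 (163 ± 72.9 and 706 ± 297). Next came Kcnd3 (254 ± 161 and 1453 ± 635), Kcnj5 (3.26 ± 1.78 and 34.2 ± 12.4), Kcns3 (205 ± 122 and 819 ± 194) and Kcnf1 (24.96 ± 17.6 and 163 ± 79.9), with adjusted p from 0.000288 to 0.00204. Also higher were Kcnd2 (24.9 ± 6.64 against 8.58 ± 5.23, log2 fold change 1.56, SE 0.40, adjusted p = 0.0154) and Kcnma1 (681 ± 201 against 332 ± 137, log2 fold change 1.09, SE 0.29, adjusted p = 0.0189). Without SNL plus UNC0638 replicate 1, the potassium list had 29 members higher and 2 lower, and Kcnd2 and Kcnma1 missed the threshold (adjusted p 0.056 and 0.075); Kcnma1 also missed it without SNL replicate 1 (adjusted p 0.053) and with the replicate number as a block (log2 fold change 0.97, adjusted p = 0.0511). With the model term, 14 members were higher and 2 lower, and Kcnd2 and Kcnma1 missed the threshold (log2 fold change 0.86, SE 0.41, adjusted p = 0.205, and 0.59, SE 0.29, adjusted p = 0.221).

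In brackets are counts adjusted over the list alone. Voltage-gated sodium channel genes gave 7 higher and 0 lower of 14 (7 and 1), with Scn10a at 9527 ± 3726 against 1744 ± 1408 and Scn11a at 5861 ± 2601 against 699.9 ± 588. Calcium channel genes gave 9 higher and 1 lower of 21 (12 and 1), and Cacna2d1 was lower (4368 ± 1911 against 13093 ± 2070.4). Nociceptor markers gave 12 higher and 3 lower of 24 (16 and 3), with a camera adjusted p of 0.000105, and 0.524 with an estimated correlation, with Htr3a 11.04-fold higher. Large-diameter neuron markers gave 7 higher and 0 lower of 18 (9 and 0). With the model term the called members of this list went from 7 to 0, those of the calcium channel genes from 10 to 4 and those of the inhibitory receptor genes, given next, from 11 to 3. Inhibitory G protein-coupled receptor genes gave 11 higher and 0 lower of 23 (11 and 1), with Cnr1 at 394 ± 122.8 against 189 ± 79.8 (adjusted p = 0.0184). The Cnr1 call was lost without SNL replicate 1, SNL plus UNC0638 replicate 1 or SNL plus UNC0638 replicate 3 (adjusted p 0.053 to 0.073). TRP, ASIC, P2X, HCN and Piezo channel genes gave 9 higher and 1 lower of 27 (11 and 1), with Trpv1 at 1881 ± 589 against 519 ± 256. GABA-A and ionotropic glutamate receptor genes gave 9 higher and 1 lower of 24 (10 and 1). Synaptic vesicle and exocytosis genes gave 5 higher and 3 lower of 24 (5 and 4).

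Injury and regeneration genes, with the counts adjusted over the list alone in brackets as for the other lists, gave 0 higher and 26 lower of 33 (0 and 28), with a median log2 fold change of -1.85 (camera adjusted p = 1.06e-10, and adjusted p = 0.524 with an estimated correlation). The small heat shock protein gene Hspb1 stood at 2038 ± 418 against 7620.1 ± 1632 (log2 fold change -1.90, SE 0.18, adjusted p = 0.000159). Gadd45a stood at 605 ± 292 against 2208 ± 481, and the GDNF receptor gene Gfra1 at 4592 ± 1152 against 9345 ± 1242. Ribosomal protein genes were lower, 0 higher and 73 lower of 80 (0 and 78), with a median of -0.73 (camera adjusted p = 1.60e-25, and adjusted p = 0.524 with an estimated correlation). Rps15 stood at 931 ± 60.6 against 2457 ± 152, Rpl13 at 1839 ± 14.3 against 4196 ± 600.1 and Rps16 at 263 ± 29.5 against 2216 ± 903. Replication-dependent histone genes gave 0 higher and 13 lower of 22 (0 and 19). Red blood cell genes gave 1 higher and 5 lower of 9 (1 and 6), with the haemoglobin genes Hba1 and Hba2 6.52-fold and 4.26-fold lower. How reads shared by near-identical genes were assigned is not given in the sources used here, which leaves the values of haemoglobin, ribosomal protein, histone and Mas-related receptor genes uncertain.

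Bracketed counts are those adjusted over the list alone. Macrophage markers as a list had 2 higher and 0 lower of 23 (2 and 0), a median log2 fold change of 0.19 and no call by camera (adjusted p = 0.304). Without SNL plus UNC0638 replicate 1 the list was called higher (camera adjusted p = 0.0116, and 0.857 with all libraries and an estimated correlation). The members that passed were Cd14, a lipopolysaccharide coreceptor (241 ± 116 against 57.3 ± 13.5), and the scavenger receptor gene Cd163 (294 ± 113 against 111 ± 20.4). Both calls were lost with a model term that set Sham replicate 3, SNL replicate 3 and all SNL plus UNC0638 libraries apart: the log2 fold change of Cd14 went from 1.97, SE 0.40, to 1.59, SE 0.48, adjusted p = 0.0565, and that of Cd163 from 1.36, SE 0.31, to 1.13, SE 0.39, adjusted p = 0.0843. Neutrophil markers gave 2 higher and 0 lower of 7 (2 and 0), and the growth factor receptor gene Csf3r stood at 454 ± 81.4 against 45.4 ± 10.1 (log2 fold change 3.30, SE 0.29, adjusted p = 0.000136). Interferon response genes went both ways, 4 higher and 2 lower of 28 (4 and 2), with a median log2 fold change of 0.30 and no call by camera (adjusted p = 0.209). The list was called higher without SNL plus UNC0638 replicate 1 (0.51, adjusted p = 0.00546) or SNL replicate 4 (0.44, adjusted p = 0.0193), though with all libraries and an estimated correlation the adjusted p was 0.819. Irf1 (1122 ± 500.2 against 401 ± 64.9) and the peptide transporter gene Tap1 (1147 ± 579 against 409 ± 41.7) were higher, and Mx2 (1042 ± 494 against 3599.6 ± 902) was lower. T and NK cell markers gave 4 higher and 1 lower of 17 (7 and 1). B cell markers gave 0 higher and 0 lower of 3 (0 and 0), with a median and a mean that differed in sign. Endothelial and mural cell markers gave 4 higher and 1 lower of 16 (4 and 2). The 4 higher T and NK cell calls fell to 0 without any 1 of SNL replicates 2, 3 or 4 or SNL plus UNC0638 replicates 2 or 3, and were 7 without Sham replicate 3. Fibroblast and matrix genes gave 0 higher and 8 lower of 19 (0 and 8), with a camera adjusted p of 0.000620, and 0.538 with an estimated correlation. Lum stood at 1029 ± 347 against 4205 ± 2282, Postn at 480.5 ± 284 against 1512 ± 509 and Mmp2 at 778 ± 195 against 1791 ± 506. The 8 fell to 5 without SNL plus UNC0638 replicate 1 or SNL replicate 1, and the camera call was lost without the former (adjusted p = 0.0516). The Lum call was lost with the term named above (log2 fold change from -1.90, SE 0.39, to -1.21, SE 0.37, adjusted p = 0.0593).

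The remaining lists are given with the counts adjusted over the list alone in brackets. Cell cycle genes gave 0 higher and 5 lower of 23 (0 and 5). Cholesterol synthesis genes gave 1 higher and 5 lower of 22 (1 and 5). Immediate early genes gave 0 higher and 2 lower of 17 (0 and 2). Myelin genes gave 0 higher and 4 lower of 17 (0 and 4). Satellite glia markers gave 1 higher and 0 lower of 13 (0 and 0). Schwann repair genes gave 0 higher and 0 lower of 11 (0 and 0). Markers of central oligodendrocytes and astrocytes gave 2 higher and 1 lower of 11 (2 and 1). Skeletal muscle genes gave 1 higher and 0 lower of 7 (1 and 0). The 1 was Pvalb, shared with the large-diameter list (671 ± 711 against 111 ± 169.5, log2 fold change 3.33, SE 0.97, adjusted p = 0.0257). Among the alternatives with libraries left out, the replicate block or the model term, its call was lost in 7. These included the fit without SNL plus UNC0638 replicate 1 (adjusted p = 0.102) and that with the model term (log2 fold change from 3.33, SE 0.97, to 1.83, SE 1.13, adjusted p = 0.329). Germline genes gave 0 higher and 0 lower of 3 (0 and 0). The myelin gene Cnp was lower (3888 ± 1181 against 6969 ± 859). Histone and DNA methylation enzymes gave 4 higher and 3 lower of 25 (4 and 3), and neither Ehmt2 (1237 ± 277, adjusted p = 0.662) nor Ehmt1 (638 ± 51.3, adjusted p = 0.549) passed.

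The genes with the highest log2 fold changes were Nos2, Mrgprd (5.08), the itaconate synthesis gene Irg1 (4.98), Mrgprb4 (4.71), the chemokine gene Ccl20 (4.66) and Mrgprx1 (4.62). Those with the lowest were Csrp3 (-4.13), Vip (-4.10), Crisp1 (-4.08), Npy (-3.88), Prlhr (-3.35) and the galanin gene Gal (-3.26, 453 ± 366 against 2756 ± 652). In SNL plus UNC0638 replicates 1, 2 and 3 Vip was at 8.07, 476.5 and 1032 and Npy at 20.6, 908 and 1624. Crisp1 was at 1.79, 172 and 347 and Csrp3 at 3.59, 130 and 120. The size of these changes thus rests in large part on replicate 1. The calls of Vip and Crisp1 were lost without SNL replicate 1, 2 or 4, and that of Npy without SNL replicate 1 or 2 (adjusted p 0.050 to 0.068). Those of Vip and Crisp1 were also lost with the replicate number as a block (adjusted p = 0.0584 and 0.0515), and all 3 without replicates 3 of Sham and SNL (adjusted p 0.056 to 0.072). The count of 3356 genes fell to 2032 without SNL plus UNC0638 replicate 2 and to 2076 without SNL replicate 1. It was 5341 without replicate 3 of Sham and of SNL, and 1286 with a model term that set those libraries and all SNL plus UNC0638 libraries apart. With that term, 14 potassium channel genes were higher and 2 lower, and 15 injury genes were lower. Several named genes kept their direction with it but missed the threshold. The change of Atf3 was about as large and its SE larger (log2 fold change from -2.56, SE 0.56, to -2.42, SE 0.76, adjusted p = 0.0722), as for Vip (-3.73, SE 1.70, adjusted p = 0.191), Crisp1 (-3.86, SE 1.68, adjusted p = 0.172) and Npy (-3.59, SE 1.52, adjusted p = 0.163). Gal went from -3.26, SE 0.70, to -2.67, SE 0.94, adjusted p = 0.104. The change was smaller for Mrgprx1 (from 4.62, SE 1.10, to 3.02, SE 1.21, adjusted p = 0.132), Kcnd2 (from 1.56, SE 0.40, to 0.86, SE 0.41, adjusted p = 0.205), Kcnma1 (from 1.09, SE 0.29, to 0.59, SE 0.29, adjusted p = 0.221) and Cnr1 (from 1.11, SE 0.30, to 0.74, SE 0.34, adjusted p = 0.183). The changes of Mrgprd (5.08 to 3.77), Ccl20 (4.66 to 3.88), Nos2 (7.01 to 6.29), Htr3a (3.47 to 2.82), Scn10a (2.68 to 1.81), Scn11a (3.28 to 2.60), Kcnd3 (2.62 to 1.95), Hba1 (-2.70 to -2.05) and Hba2 (-2.09 to -1.32) were also smaller with it, with their calls kept. Some lists lost most of their shift and their camera call with the term: the median of the large-diameter neuron markers went from 1.38 to 0.21 (adjusted p = 0.166), that of the calcium channel genes from 0.86 to 0.23 (adjusted p = 0.0945) and that of the GABA-A and glutamate receptor genes from 0.66 to 0.07 (adjusted p = 0.124). Inhibitory receptor genes went from 0.77 to 0.39 (adjusted p = 0.0874) and red blood cell genes from -1.32 to -0.87 (adjusted p = 0.148), also without a call. The potassium channel median went from 1.08 to 0.59, with the call kept. That of the nociceptor markers went from 0.855 to 0.812.

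**Figure D2:**
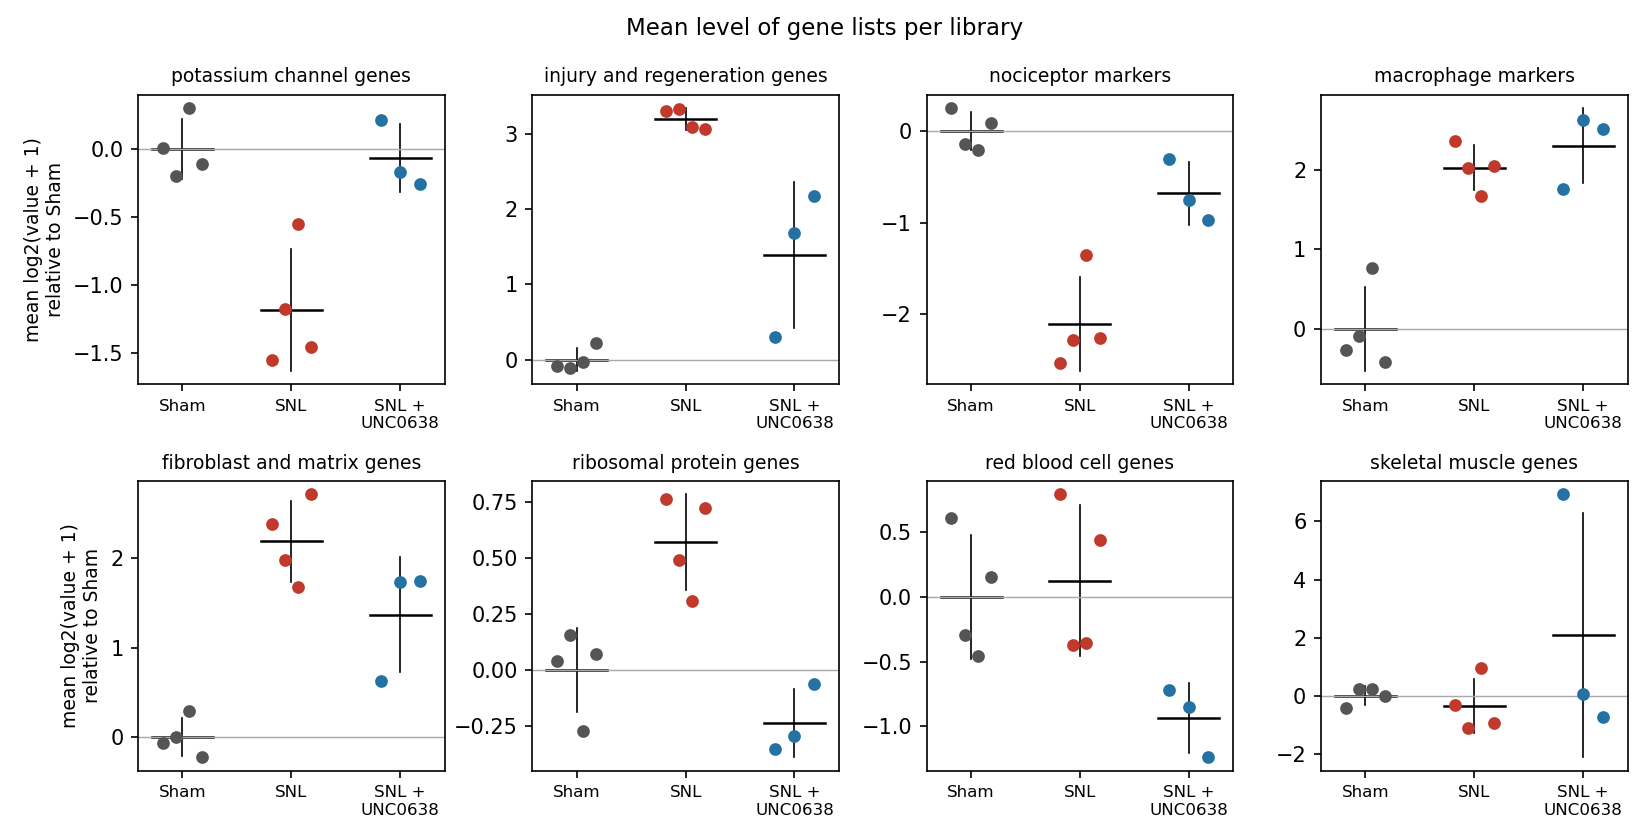
Mean log2(value + 1) of the members of 8 gene lists in each library (points), relative to the Sham mean, by group with means (horizontal lines) and SD (vertical lines). Potassium channel genes were lowest in SNL, macrophage markers were high in both ligated groups, and skeletal muscle genes were high in SNL plus UNC0638 replicate 1 (6.93).

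SNL plus UNC0638 was compared with Sham to show how far ligated ganglia with the inhibitor stayed from sham ganglia. Of the potassium and sodium channel genes, 14 and 5 were lower than in Sham, among them Kcnab1 (1529 ± 528 against 3848 ± 922, log2 fold change -1.35, SE 0.27, adjusted p = 0.00207) and Scn1a (2768 ± 1008 against 5779.8 ± 296, log2 fold change -1.12, SE 0.31, adjusted p = 0.0105). The Scn1a call was lost without SNL plus UNC0638 replicate 2 (log2 fold change -0.97, adjusted p = 0.0522). Some genes that had fallen in SNL did not pass here. Kcna4 stood at 563 ± 225 against 906 ± 36.3 (adjusted p = 0.0704) and Kcnd2 at 24.9 ± 6.64 against 44.6 ± 11.99 (adjusted p = 0.114). With the term for replicate 3 of Sham and SNL both were called lower (Kcna4 at log2 fold change -1.22, SE 0.36, adjusted p = 0.0188, and Kcnd2 at -1.50, SE 0.41, adjusted p = 0.0141). Kcnma1 was at 681 ± 201 against 768 ± 145 (adjusted p = 0.601) and Oprm1 at 359 ± 103 against 359.8 ± 54.4 (adjusted p = 0.954). Cnr1 was not called (log2 fold change -0.75, SE 0.30, adjusted p = 0.0510), but was called lower with that term (-1.12, SE 0.34, adjusted p = 0.0209). Atf3 remained higher, 1487 ± 1098 against 169.8 ± 7.80 (log2 fold change 2.62, SE 0.56, adjusted p = 0.00269). Csf3r stood at 454 ± 81.4 against 20.7 ± 9.20 (log2 fold change 4.45, SE 0.29, adjusted p = 2.28e-05), above its level in SNL as well, and Gfap, an astrocyte and satellite glia gene, at 3825 ± 2115 against 265 ± 119. In all, 6220 genes passed, 3083 higher and 3137 lower, with 1797 and 624 changed at least 2-fold.

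Of the 79 potassium channel genes, 14 were higher and 14 lower (9 and 9 adjusted over the list alone), with a median log2 fold change of -0.19 and no call by camera (adjusted p = 0.584). Kcng4 was 4.60-fold higher and Kcnab1 2.54-fold lower. A missed threshold, as for Kcna4, Kcnd2 and Kcnma1, does not show equal levels. The 28 calls were 18 without Sham replicate 4 (9 and 9), 16 without SNL plus UNC0638 replicate 2 (10 higher, 6 lower) and 13 without its replicate 3 (8 higher, 5 lower), and 9 were lower without Sham replicate 1. With the term for replicate 3 of Sham and SNL, 33 were lower and 7 higher. Without replicate 3 of Sham and SNL and SNL plus UNC0638 replicate 1, 26 were lower. Brackets hold the counts adjusted over the list alone. Sodium channel genes gave 2 higher and 5 lower of 14 (2 and 5), with Scn3a higher (48.1 ± 21.0 against 17.9 ± 5.82), a call lost with that term (log2 fold change from 1.31, SE 0.34, to 1.11, SE 0.43, adjusted p = 0.0556). Calcium channel genes gave 4 higher and 2 lower of 21 (0 and 0). Nociceptor markers gave 1 higher and 8 lower of 24 (1 and 8). Large-diameter neuron markers gave 0 higher and 6 lower of 18 (0 and 5), with Nefl at 37845 ± 13779 against 121310 ± 11559. The median of these markers, -0.57 and not called by camera (adjusted p = 0.0871), was -1.65 and called with the term (adjusted p = 7.39e-06), and was also called with the replicate block (-0.75, adjusted p = 0.0302) and without SNL plus UNC0638 replicate 1 (-0.84, adjusted p = 0.0331), Sham replicate 1 (-0.65, adjusted p = 0.0449) or SNL replicate 3 (-0.57, adjusted p = 0.0324). The 8 nociceptor markers became 5 without Sham replicate 1 or SNL plus UNC0638 replicate 3. Inhibitory G protein-coupled receptor genes gave 0 higher and 3 lower of 23 (0 and 3), with a median of -0.45 that was called with the term (-0.80, adjusted p = 0.00626) and without SNL plus UNC0638 replicate 1 (-0.73, adjusted p = 0.0474). With an estimated correlation neither list was called (adjusted p = 0.802 for the large-diameter and 0.719 for the inhibitory receptor list, with all libraries and no term), and such a correlation was not estimated for these alternatives. Synaptic vesicle genes gave 0 higher and 9 lower of 24 (0 and 9). TRP, ASIC, P2X, HCN and Piezo channel genes gave 7 higher and 3 lower of 27 (7 and 2). GABA-A and glutamate receptor genes gave 7 higher and 7 lower of 24 (7 and 7). In both of these lists and in the central glia list the median and the mean differed in sign.

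In brackets, as before, are the counts adjusted over the list alone. Injury and regeneration genes gave 19 higher and 1 lower of 33 (20 and 1), with a camera adjusted p of 0.000229, and 0.538 with an estimated correlation. The 19 fell to 11 without SNL plus UNC0638 replicate 2 and to 10 without replicate 3. Macrophage markers gave 23 higher and 0 lower of 23 (23 and 0), with a median log2 fold change of 2.34 (camera adjusted p = 2.43e-11, and adjusted p = 0.524 with an estimated correlation) and Cd74 at 7159 ± 2233 against 1111 ± 517. T and NK cell markers gave 16 higher and 0 lower of 17 (17 and 0). B cell markers gave 3 higher and 0 lower of 3 (3 and 0). Neutrophil markers gave 5 higher and 0 lower of 7 (5 and 0). Interferon response genes gave 13 higher and 1 lower of 28 (14 and 1), with Irf1 5.17-fold and Tap1 4.53-fold higher. The 5 neutrophil markers became 3 without SNL plus UNC0638 replicate 2. Fibroblast and matrix genes gave 15 higher and 0 lower of 19 (15 and 0). Endothelial and mural cell markers gave 14 higher and 0 lower of 16 (14 and 0). Cell cycle genes gave 13 higher and 0 lower of 23 (13 and 0), with Mki67, a proliferation marker, at 374 ± 109.5 against 95.5 ± 16.6. Immediate early genes gave 14 higher and 0 lower of 17 (15 and 0), with Fos at 408 ± 163 against 72.9 ± 23.2. Histone and DNA methylation enzymes gave 12 higher and 2 lower of 25 (12 and 2). The demethylase gene Kdm6b (5.52-fold), Ezh2 (3.37-fold), Ehmt1 (1.45-fold) and Ehmt2 (1.48-fold, adjusted p = 0.0166) were higher. The Ehmt2 call was lost without SNL plus UNC0638 replicate 2 (adjusted p 0.090) and with the term (log2 fold change from 0.57, SE 0.17, to 0.30, SE 0.18, adjusted p = 0.187), with which Kdm6b also went from 2.46, SE 0.49, to 1.31, SE 0.32, adjusted p = 0.00824.

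With the counts adjusted over the list alone in brackets, cholesterol synthesis genes gave 0 higher and 13 lower of 22 (0 and 13), with a camera adjusted p of 0.00186, and 0.524 with an estimated correlation, and with the regulator gene Insig1 at 2039 ± 80.3 against 3316 ± 238. Ribosomal protein genes gave 1 higher and 15 lower of 80 (0 and 10), with a median of -0.15 (camera adjusted p = 0.0190, and adjusted p = 0.810 with an estimated correlation). The median reversed to 0.12 with the term (adjusted p = 0.299), and its call was lost without Sham replicate 2 (-0.09, adjusted p = 0.0604) or SNL plus UNC0638 replicate 1 (-0.07, adjusted p = 0.199), while the 15 lower genes became 24 without Sham replicate 3. Red blood cell genes gave 0 higher and 5 lower of 9 (0 and 5). Histone genes gave 7 higher and 2 lower of 22 (4 and 1). Satellite glia markers gave 6 higher and 2 lower of 13 (7 and 4). Myelin genes gave 5 higher and 1 lower of 17 (1 and 0). Schwann repair genes gave 4 higher and 0 lower of 11 (4 and 0). Skeletal muscle genes gave 1 higher and 0 lower of 7 (1 and 0), and Pvalb did not pass (671 ± 711 against 1399.7 ± 304, adjusted p = 0.193). Central glia markers gave 2 higher and 0 lower of 11 (1 and 0). Germline genes gave 0 higher and 1 lower of 3 (0 and 1). The genes with the highest log2 fold changes were Nos2 (6.66), Tnfrsf14 (6.40), the anchoring fibril collagen gene Col7a1 (6.32), Irg1 (5.77), Lilrb4 (5.37) and the decoy receptor gene Il1r2 (5.35). Those with the lowest were Hes5 (-3.28), the respiratory chain gene Ndufb7 (-2.60, 156 ± 49.6 against 929 ± 145), Hba1 (-2.55), Pnlip (-2.45), Rlbp1 (-2.37) and the copper chaperone gene Cox17 (-2.31). With the term the log2 fold change of Col7a1 went from 6.32 to 4.91, that of Nos2 from 6.66 to 5.94, that of Il1r2 from 5.35 to 6.33 and that of Hba1 from -2.55 to -1.89, all with their calls kept.

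**Figure D3:**
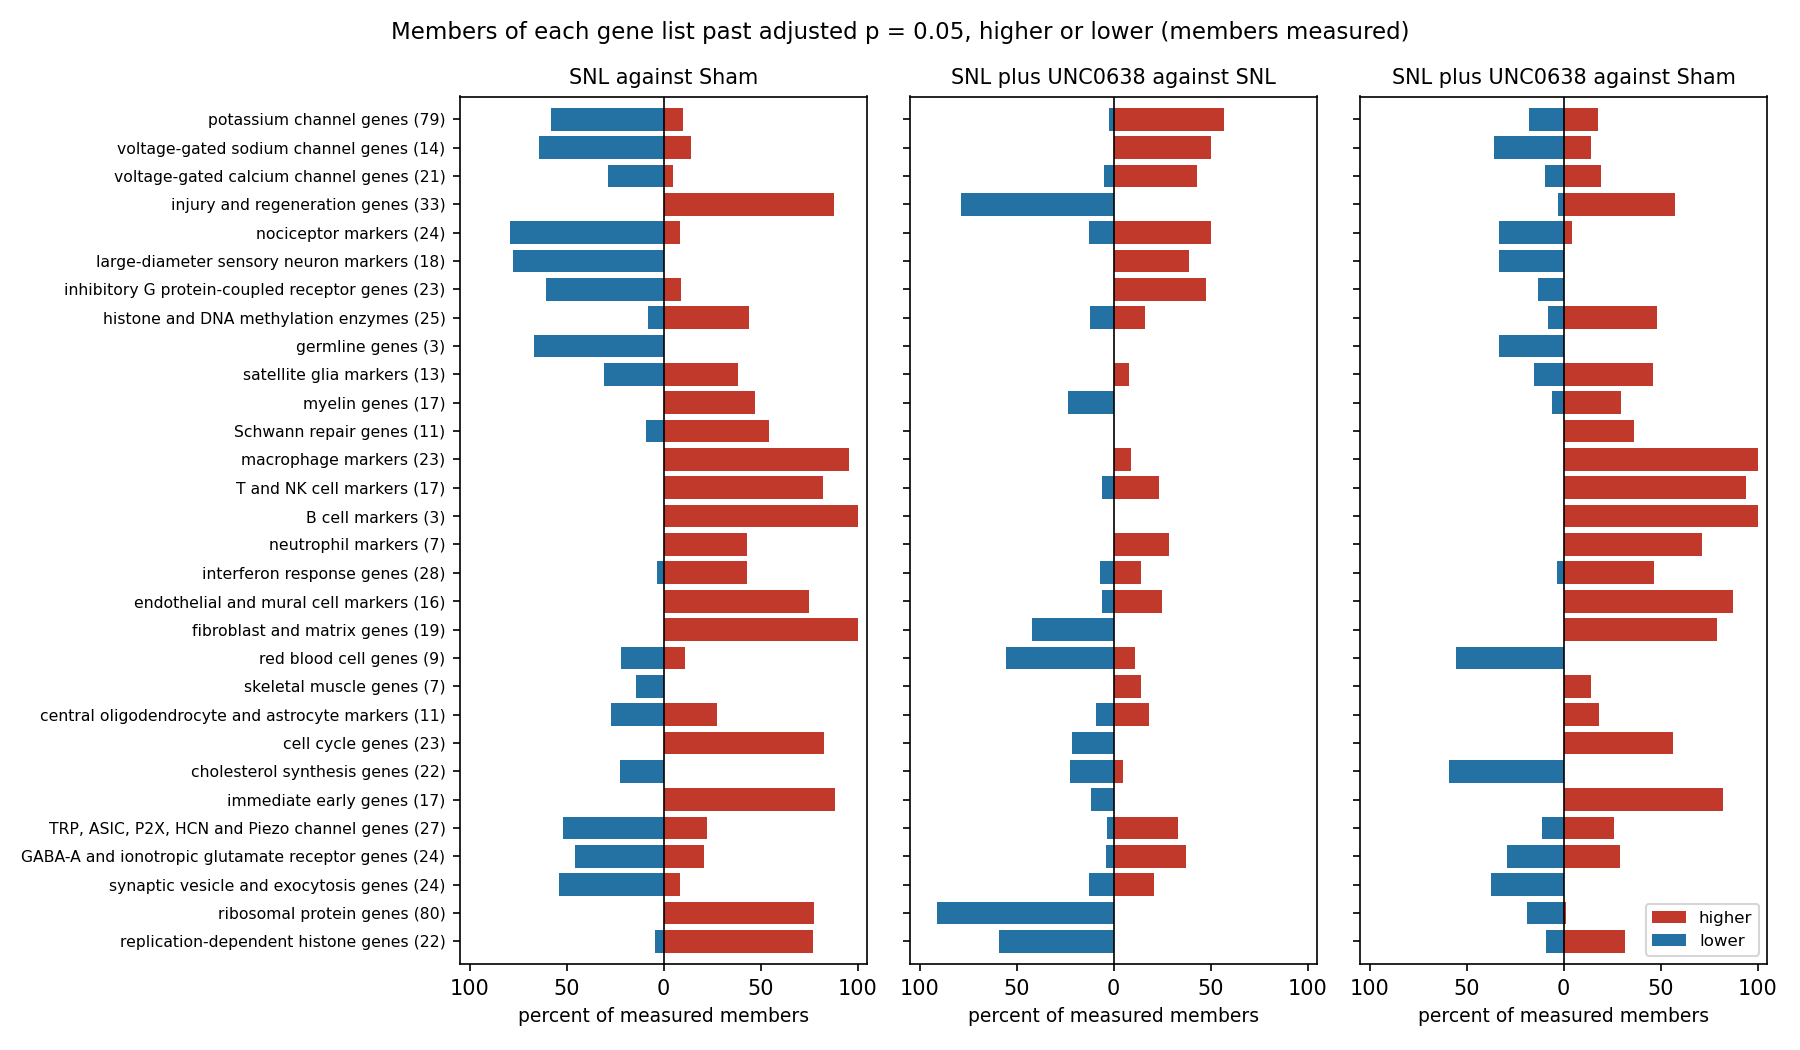
Percent of the measured members of the gene lists (number measured in brackets) with limma adjusted p under 0.05, higher (red, to the right) or lower (blue, to the left), in the 3 comparisons. Of 79 potassium channel genes, 46 were lower in SNL than in Sham and 45 were higher in SNL plus UNC0638 than in SNL.

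How far the differences with UNC0638 ran against those of ligation was measured across all tested genes. The log2 fold change of SNL plus UNC0638 against SNL had a slope of -0.30 on that of SNL against Sham when the SNL libraries were split so that none was in both (-0.38 to -0.18 over the 6 splits), where 100 simulations with no effect gave -0.002. The simulated noise was independent between genes, so that the -0.002 does not show what deviations shared across genes would give. Unsplit, the slope was -0.33 against -0.50 in the simulations, and the covariance -0.338 against a simulated -0.0399. The slope was -0.15 without SNL plus UNC0638 replicate 1, and for single libraries of this group it was -0.59, -0.18 and -0.13. Of the 2828 genes lower in SNL, among them Kcna4, Scn10a and Mrgprd, 700 were higher with UNC0638, where independent lists would share 381, and 165 were lower still. Of the 2995 genes higher in SNL, among them Atf3, Vip and Npy, 712 were lower with UNC0638, where independent lists would share 428, and 250 were higher still. With the SNL libraries split, the means were 343 (139.9 of independent lists) and 281 (133). Over the 6 splits the lowest were 152 (60.1 of independent lists in that split) and 143 (47.0). Without SNL plus UNC0638 replicate 1, and with the SNL libraries not split, the overlaps were 360 (277 of independent lists) and 438 (330.4). All SNL libraries then enter both comparisons with opposite sign, which raises such overlaps, so that these counts alone do not show a reversal.

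Against Sham, 1733 of the 2828 genes lowered by ligation (61.3%) were also lower in SNL plus UNC0638, where independent lists would share 734, and 1925 of the 2995 raised genes (64.3%) were also higher, where they would share 764. Both comparisons use the Sham libraries: with these split, the means were 926 (377 of independent lists) and 1213 (464). In 20 simulations with no effect 0.35 genes were called on average after adjustment. Their noise was independent between genes and libraries, without the deviations across genes seen in replicates 3 of Sham and SNL. The 0.35 is therefore no error rate for these data. On genes changed at least 4-fold by ligation with a mean value of at least 50, each library was placed between the mean of Sham (0) and that of SNL (1). A Sham or SNL library was left out of its own group mean. SNL plus UNC0638 replicates 2 and 3 lay at 0.844 and 0.806 on 234 raised genes and at 0.636 and 0.724 on 193 lowered genes, and replicate 1 at 0.225 and 0.262. Gene groups lay apart among the genes that met these limits. In SNL plus UNC0638 replicates 1, 2 and 3, 19 of 79 potassium channel genes had a median position of 0.114, 0.581 and 0.658. For 19 of 33 injury genes it was 0.00982, 0.268 and 0.354, and for 15 of 23 macrophage markers 0.61, 1.60 and 1.36. The mean of all 79 potassium channel genes was 0.22, -0.17 and -0.25 from the Sham mean on the log2 scale. It was -0.20 to 0.30 in the Sham libraries and -1.55 to -0.55 in the SNL libraries.

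**Figure D4:**
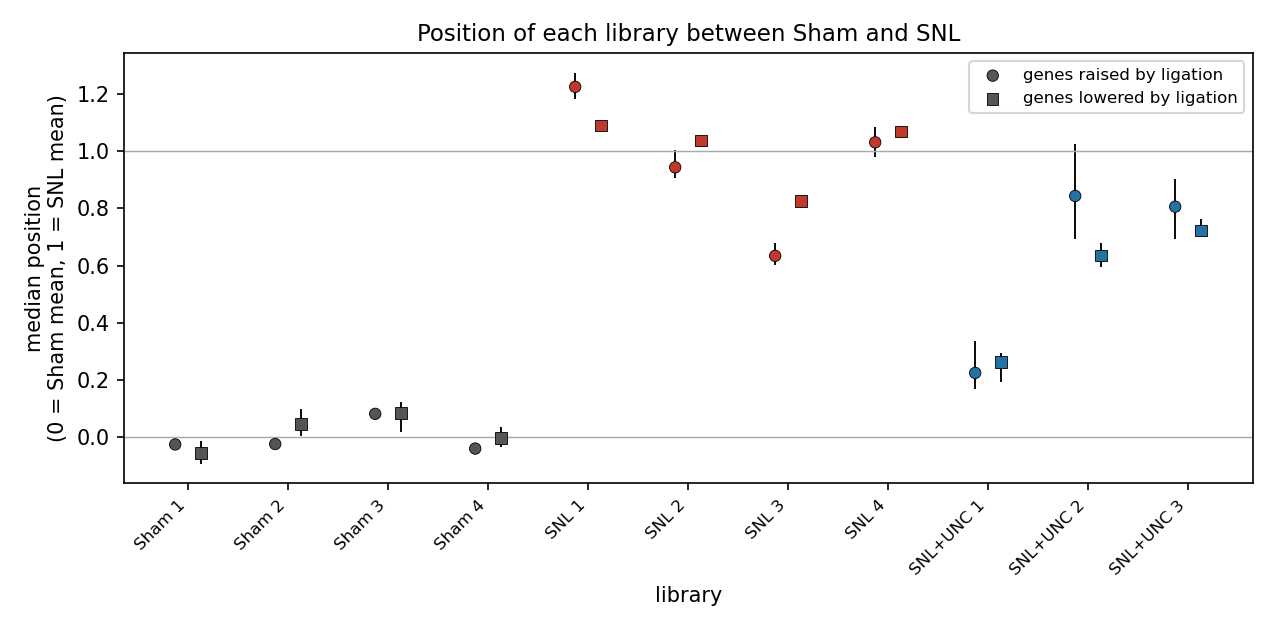
Median position of each library between the Sham mean (0) and the SNL mean (1), over genes changed at least 4-fold by ligation (circles, 234 raised genes; squares, 193 lowered genes), coloured by group, with 95% bootstrap intervals over genes (vertical lines). A Sham or SNL library was left out of the mean of its own group. SNL plus UNC0638 replicate 1 lies at 0.225 and 0.262, and replicates 2 and 3 lie from 0.636 to 0.844.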

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

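The rule for single libraries and the counts of other splits were set before the data were examined; the tests on Per1 and Per2 were chosen after the result was seen. In 238 groups of 4 libraries, 25 had a library whose gap to the nearest other, over the whole range, exceeded Dixon's 95% critical value, where chance gives about 11.9. Genes share libraries, so that these are not independent. SNL replicate 3 stood apart in 11, Sham replicate 3 in 12, and SNL replicate 1 and Sham replicate 2 in 1 each.

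Among the genes reported here, SNL replicate 3 had higher values than the other SNL libraries of these genes lowered by ligation: Mrgprd (27.8 against 0 to 1.88), Mrgprb4 (29.3 against 0.912 to 5.64), Chrna3 (90.9 against 5.47 to 9.86), Hapln4 (185 against 3.65 to 6.86), Sptssb (19.5 against 0 to 1.72), Kcna4 (217 against 77.5 to 99.0), Scn11a (1575 against 307 to 479), Htr3a (376 against 64.0 to 73.9) and Pvalb (364 against 9.12 to 36.0). It was lower for Gal (1788 against 2991 to 3205) and higher for the clock gene Per2 (287 against 91.7 to 96.9). On genes changed at least 4-fold by ligation its median position was 0.634 of the way from Sham to SNL for raised and 0.826 for lowered genes, and 0.944 to 1.22 in the other SNL libraries. SNL replicate 1 stood apart for Rps16 (3559 against 1656 to 1923).

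Sham replicate 3 had higher values than the other Sham libraries of Hapln4 (1256 against 385 to 479.6), Gfra1 (3716 against 3415 to 3443), Oprm1 (441 against 326 to 339), Cd74 (1885 against 813 to 876), Gfap (442 against 199.8 to 211), Col7a1 (18.7 against 1.14 to 1.54), Fos (108 against 59.1 to 65.3), Kdm6b (376 against 81.8 to 103), Per1 (435 against 128 to 153) and Per2 (249 against 53.8 to 71.6). It was lower for Hes5 (43.6 against 83.0 to 89.8). The mean of the large-diameter sensory neuron markers in it was 0.77 above the Sham mean on the log2 scale, against -0.37 to -0.19. Sham replicate 2 stood apart for Prlhr (7.95 against 2.78 to 3.12). No biological explanation of these single libraries was tested.

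The libraries of each comparison were also split in all 35 ways into groups of the same sizes. For SNL against Sham 1 split gave as many genes as the real 5823, the real one itself, and the highest other gave 0. This argues against a grouping by chance, though 1 of 35 is the lowest share that 35 splits can give. For SNL plus UNC0638 against SNL it was 1 of 35, with 3356 genes against 2655 in the highest other split. For SNL plus UNC0638 against Sham it was 1 of 35, with 6220 against 5642. The real split ranked first in both, but another split also gave many genes, so that these counts do not exclude chance. The highest other splits set SNL replicates 1, 2 and 4 apart from SNL replicate 3 and the SNL plus UNC0638 libraries, and Sham replicates 1, 2 and 4 apart from Sham replicate 3 and these libraries. They point to a structure in which replicates 3 of Sham and SNL share part of what sets the SNL plus UNC0638 libraries apart. With a term for it, the real comparisons gave 1286 and 5120 genes.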

How the results depend on the processing

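Alternatives with TMM scaling, other pseudocounts, replicates 3 left out and the term for Sham replicate 3, SNL replicate 3 and SNL plus UNC0638 were chosen after the result was seen; the others were set before the data were examined. The planned edgeR test was not run, nor was DESeq2, since the values are not counts. For named genes, 10051 of 10434 results under an alternative kept the call, or the lack of one, of the report. Another 336 lost a call, 47 gained a call and 0 called results reversed. For list medians it was 2268 of 2430, with 103 calls lost, 58 gained and 1 called result reversed. Direction was compared only for results called in the report. Uncalled results could change sign, as Ehmt2 did in SNL plus UNC0638 against SNL (log2 fold change 0.11, and -0.16 with the term). Of 156 counts by direction, 139 stayed within 1.5 times. No scaling moved the median log2 fold change of all genes by 0.1, and with TMM the share of called genes that were higher in SNL plus UNC0638 than in SNL was 41.2% in place of 48.6%.

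Genes changed in SNL plus UNC0638 against SNL numbered 2126 with the replicate block (5342 in SNL against Sham and 5437 in SNL plus UNC0638 against Sham), 1303 with treat against a 1.2-fold change, 1304 at an adjusted p under 0.01, 5341 without replicates 3 of Sham and SNL, 5220 without these and SNL plus UNC0638 replicate 1, and 1286 with the term. A test against a 1.2-fold change and a lower threshold call fewer genes by construction: they gave 3437 and 3780 in SNL against Sham, 3837 and 4129 in SNL plus UNC0638 against Sham, and 17 potassium channel genes in the latter with treat. With limma-voom the counts were 7639, 4828 and 7690.

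With the term, potassium channel genes called in SNL plus UNC0638 against SNL numbered 16, and their median in SNL plus UNC0638 against Sham was -0.72 and called (adjusted p 0.00507, against 0.207 to 0.999 in the other alternatives with the preset correlation). The median of the ribosomal protein genes in SNL plus UNC0638 against Sham reversed with it to 0.12 (adjusted p 0.299). The term is estimated from Sham replicate 3 and SNL replicate 3 alone, and the cause was not tested. With an estimated correlation the potassium medians of -1.28 and 1.08 had adjusted p of 0.538 and 0.524, and no list kept its call.

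With 1 library left out at a time, genes changed ranged from 4794 to 6510 in SNL against Sham, from 2032 (without SNL plus UNC0638 replicate 2) to 4468 (without Sham replicate 3) in SNL plus UNC0638 against SNL, and from 4589 to 6951 in SNL plus UNC0638 against Sham. Potassium channel genes called ranged from 50 to 57, from 31 (without SNL plus UNC0638 replicate 1) to 52, and from 13 (without its replicate 3) to 33, with medians of -1.51 to -1.12, 0.84 to 1.18 and -0.42 to -0.08. The slope of the differences with UNC0638 on those of ligation ranged from -0.38 to -0.15, the latter without SNL plus UNC0638 replicate 1. The effect of depth was not tested: genes with low values were left out by the filter, which kept 12085 of 16811 genes, and 1970 of the others were at 0 in every library.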

Other observations

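Of the tests below, that of skeletal muscle on the genes higher in both comparisons was set before its result was seen, and the others were chosen after the result was seen. Genes Il1b, Tnf, Lcn2, Hmox2-ps1, Per1, Per2, Per3, Cry1, Cry2 and Slc25a37 were chosen after their values were seen. Some single genes stood higher in SNL plus UNC0638 than in either other group, beside Nos2, Irg1, Ccl20 and Csf3r. The cytokine gene Il1b was at 9.72 ± 2.55 in Sham, 30.8 ± 8.87 in SNL and 238 ± 37.9 in SNL plus UNC0638 (log2 fold change 2.95, adjusted p = 0.000213 against SNL), Tnf at 3.74 ± 1.04 in Sham, 7.09 ± 1.999 in SNL and 50.9 ± 15.9 in SNL plus UNC0638 (log2 fold change 2.67, adjusted p = 0.000774), and the lipocalin gene Lcn2 at 35.0 ± 9.94 in Sham, 42.3 ± 31.3 in SNL and 288 ± 63.1 in SNL plus UNC0638 (log2 fold change 2.95, adjusted p = 0.00103, and 2.28 with the term for replicates 3 of Sham and SNL). Hmox2-ps1, named as a pseudogene of a haem oxygenase, had 1441 ± 488 in Sham, 2142 ± 778 in SNL and 12154 ± 779.8 in SNL plus UNC0638 (log2 fold change 2.57, adjusted p = 0.000307). In all, 839 genes were higher in SNL plus UNC0638 than in both other groups, where independent lists would share 416, and 927 were lower, where they would share 448. The SNL plus UNC0638 libraries are in both comparisons, which raises such overlaps. Of the lists, ribosomal protein genes (15 members, adjusted p = 0.0306, Fisher's exact test) and red blood cell genes (4 members, adjusted p = 0.0444) were over-represented among the genes lower than both. This test takes the members of a list as independent, while their estimated correlations were 0.590 and 0.356, and the ribosomal median against Sham reversed to 0.12 with the term, so that these 2 results may be overstated. Potassium channel genes had 0 members there (adjusted p = 0.0444 by the same test, fewer than by chance). Their estimated correlation was 0.278, so that this result too may be overstated. No list was over-represented among the genes higher than both (lowest adjusted p = 0.197, for a deficit of ribosomal protein genes). The immune lists were not either, with adjusted p of 0.274 for T and NK cell, 0.62 for neutrophil and 1 for macrophage markers and 0.777 for interferon response genes.

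Of 11 genes of the circadian clock, 4 passed against SNL (Per2, Per3, Cry1 and Cry2, all higher) and 7 did not. Per2 was at 110 ± 93.2 in Sham, 142 ± 96.3 in SNL and 662 ± 77.8 in SNL plus UNC0638 (log2 fold change 2.39, adjusted p = 0.00637 against SNL, and log2 fold change 2.87, adjusted p = 0.000929 against Sham), Per3 at 146 ± 71.9 in Sham, 196 ± 92.5 in SNL and 589 ± 67.6 in SNL plus UNC0638 (log2 fold change 1.69, adjusted p = 0.00823 against SNL), Cry1 at 111 ± 21.4 in Sham, 83.9 ± 28.4 in SNL and 250.2 ± 31.0 in SNL plus UNC0638 (log2 fold change 1.62, adjusted p = 0.00155 against SNL) and Cry2 at 674 ± 173 in Sham, 463 ± 155 in SNL and 735 ± 81.7 in SNL plus UNC0638 (log2 fold change 0.71, adjusted p = 0.0432 against SNL). Per1 was at 214 ± 147 in Sham, 300.1 ± 164 in SNL and 622 ± 75.7 in SNL plus UNC0638 and did not pass against SNL (adjusted p = 0.0592), nor did Dbp, Nr1d1, Tef, Arntl, Npas2 and Clock (adjusted p 0.103 to 0.984). Replicates 3 of Sham and SNL had 249 and 287 for Per2, against 53.8 to 96.9 in the other libraries of these groups. With the term for these replicates the log2 fold change of Per2 went from 2.39, SE 0.51, to 1.06, SE 0.18, adjusted p = 0.00668, against SNL and from 2.87, SE 0.51, to 1.54, SE 0.18, adjusted p = 0.000542, against Sham, and that of Per1 against SNL from 1.18, SE 0.43, to 0.08, SE 0.20, adjusted p = 0.838. The Per3 call against SNL was lost with it (from 1.69, SE 0.38, to 0.83, SE 0.27, adjusted p = 0.0696). Times of tissue collection are not given in the sources used here.

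SNL plus UNC0638 libraries lay between Sham and SNL on genes changed by ligation, such as Atf3 and Kcna4. A mixture of ligated and unligated tissue in a single share would put all gene groups at the same position, but the macrophage markers lay above the injury and regeneration genes by at least 0.6 in each SNL plus UNC0638 library (0.6, 1.34 and 1.01), which argues against that as the whole cause. An earlier test of the same idea, the median position of lowered minus raised genes, gave 0.0376, -0.208 and -0.0825 in replicates 1 to 3, with intervals that include 0 in replicates 1 and 3 (-0.0957 to 0.103 and -0.188 to 0.0297), so that this test alone leaves a single share open in 2 of the 3. The difference that sets replicates 3 of Sham and SNL apart was also weighed: with a term for it, the median log2 fold change in SNL plus UNC0638 against SNL was -1.65, in place of -1.85, for the injury list, which argues against it as the whole cause there, but for the large-diameter neuron markers 0.153 of the change was left (1.38 to 0.21, bootstrap interval over genes 0.0182 to 0.317), so that it may account for most of theirs, and for the potassium channel genes 0.544 (1.08 to 0.59, interval 0.373 to 0.826), whose share from it and from the treatment cannot be told apart, as the term rests on 2 libraries. The nociceptor markers kept 0.95 of their change with the term (0.855 to 0.812, interval 0.72 to 1.19). Their called members went from 15 to 11. An effect of UNC0638 on the injury response of neurons may explain the pattern, and so might the reagent used for RNA extraction. Neither was tested.

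SNL plus UNC0638 replicate 1 lay closest to Sham, at 0.225 on genes raised and 0.262 on genes lowered by ligation. A ganglion without any ligation change could have a position near that of Sham on the injury list, and it was at 0.00982 (bootstrap interval 0.000229 to 0.0364). Vip (8.07), Gal (52.0) and Cacna2d1 (2474) lay within their ranges in the Sham libraries, while Atf3 (265) and Npy (20.6) lay above theirs. The mean of the list was 0.30 above the Sham mean on the log2 scale, against -0.12 to 0.22 in the Sham libraries. That of the macrophage markers was 0.99 above the highest Sham library. With no group given UNC0638 without ligation, genes raised by ligation and by UNC0638 cannot be told apart in this library, so that the explanation stays open. A wrong group label was tested on 764 genes called higher than both other groups without this library: it lay above all Sham and SNL libraries in 80.1% of them, where the highest share for a single Sham or SNL library among its 8 was 36.3%, which argues against it. Skeletal muscle genes were high in this library, with Acta1 at 12730, Ckm at 6954 and Tnnt3 at 3308, against at most 77.4 in replicates 2 and 3 (genes chosen after their values were seen). Dilution of the ganglion RNA by muscle would lower neuronal genes, but the mean of the synaptic list was 0.40 above the higher of replicates 2 and 3 on the log2 scale, which argues against dilution as the reason for the low injury genes.

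The genes higher in SNL plus UNC0638 than in both other groups, Nos2 and Csf3r among them, were weighed against blood left in the ganglia. Of 9 red blood cell genes 5 were lower against SNL and 1, Slc25a37, was 2.05-fold higher, with a median log2 fold change of -1.32 (camera adjusted p = 0.0264, and adjusted p = 0.538 with an estimated correlation), which argues against more blood as far as haemoglobin genes, whose shared reads leave their values uncertain, can show it. Skeletal muscle in SNL plus UNC0638 replicate 1 was weighed too: without this library the median change of the genes higher than both against SNL was 1.09 times that with all. Of 7 skeletal muscle genes, 0 were among them. Without that library, 625 of the 839 genes were still called higher than both. Genes high in it alone would mostly miss the threshold for their spread. The test of the median change could therefore hardly come out otherwise, and no conclusion is drawn from it. The difference that sets replicates 3 of Sham and SNL apart may contribute: the lower of their median deviations on these genes, that of SNL replicate 3, was 0.0801 of the change in SNL plus UNC0638 (bootstrap interval 0.0464 to 0.112), and that of Sham replicate 3 was 0.344 of it. With the term for it, 330 of the 839 genes (39.3%) remained higher than both, so that its share and that of the treatment cannot be told apart for the rest. An effect of UNC0638 and the reagent used for RNA extraction also stay open and were not tested.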
